A study of Mus musculus with 12 samples.

How the data were processed

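RNA of mandibular lymph nodes was sequenced in 12 libraries, 3 in each of 4 groups. Per the labels, RNA was extracted with RNeasy kits and libraries of total RNA were made with the NEBNext Ultra II Directional kit. The values are estimated counts per gene in the table the authors deposited, with 56,941 Ensembl mouse gene IDs. Per the submitters' processing notes, reads were trimmed with fastp 0.23.2, aligned with HISAT2 2.2.1 to GRCm39 and assembled and quantified with StringTie 2.2.1. All values were whole numbers as deposited, so no rounding was needed here. Totals were 36.9 to 58.4 M per library, with group means ± SD of 43.2 ± 3.61 (WT_se), 45.3 ± 6.76 (WT_DTH), 50.2 ± 7.33 (KO_se) and 44.5 ± 6.77 M (KO_DTH). Of the genes, 24,767 had a count of 0 in every library.

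Gene symbols, chromosomes and 3′ UTRs came from GENCODE M21 on GRCm38, an older build than that of the table, so it served for names, gene order and UTR sequence only and no coordinates are given. Of the IDs 51,948 matched, and the 4,993 without a symbol held 0.326 to 0.543% of counts. The 3′ UTR was annotated in 21,123 genes.

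Samples were grouped by genotype and state from their labels. The labels do not say whether the 3 libraries of a group come from separate animals, so p-values measure the spread between these libraries. They also do not say what a shared replicate number means, and no block was used in the fit reported. Between libraries of 1 group the chi-squared per degree of freedom over genes was 40.5 to 334, where 1 is counting noise alone. The first 2 principal components held 23.2% and 14.6% of the variance.

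Genes were tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling, filterByExpr with a minimum count of 10), which kept 20,034 genes. One model with a mean per group was fitted to all 12 libraries, leaving 8 residual degrees of freedom. It gave 7 contrasts: challenge in each genotype, genotype in each state, their interaction and both averaged effects. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05, two-sided throughout. Log2 fold changes are given ± SE of the model, and group values as mean ± SD of CPM (edgeR's counts scaled to library size). R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used. The model, contrasts, gene lists, alternatives and the rule for naming genes, except where said below, were chosen before the data were examined.

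Of 41 gene lists written in advance 40 were tested, and the list of sex-linked genes was only described. Of 654 list entries 651 matched a gene, 4 by synonym. Lists with at least 5 measured members were tested with camera (limma) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists of a comparison. Camera was repeated with a correlation estimated per list, which kept 0 of the 19 lists called for challenge in wild type, 0 of 20 for challenge in the knockout, 0 of 19 and 0 of 13 for genotype when sensitized and challenged, 0 of 18 for the interaction, 1 of 17 for the averaged genotype effect and 0 of 19 for the averaged challenge effect. The counts given as adjusted over the list alone, or alone for short, use Benjamini-Hochberg within the members of 1 list. Seed matches are 7 bases pairing with positions 2 to 8 of miR-451a, searched in annotated 3′ UTRs. The mature sequence was typed by hand and found within the annotated hairpin. Among 14,498 tested genes with a searched UTR 327 carried a match, and 71 an 8-base match. A gene without an annotated 3′ UTR was not searched.

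The genes named are, in each comparison of 2 groups, first the genes fixed in advance, of which the text names Mir451a, Mir144, Il17a, Il17f, Il22, Il23r, Ccr6, Ifng, Tbx21, Il4, Il13, Gata3, Foxp3 and Il10. Next come, among genes past the threshold whose groups did not overlap, the 10 largest rises and 10 largest falls, leaving out predicted genes, receptor segments and genes with a higher group mean under 20 counts. Last come up to 4 members of each list called, by smallest p. For the interaction these are the 5 of smallest p in each direction. The text names a part of the genes so chosen. A fold against a group with 0 counts throughout is given as at least the ratio to 3 counts over that group.

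Alternatives set in advance were DESeq2 size factors, no filter beyond a nonzero count, a mean of at least 50 counts, the DESeq2 Wald test, only the libraries compared, a block by replicate number, each library left out in turn, camera with an estimated correlation, fry and 8-base seed matches. Alternatives added after the data were seen were a salivary score as covariate, 2 salivary components as covariates, leaving out the library of largest salivary share in each group, and sex as covariate. Settings foreseen for normalized values were not used, since the values are counts. When 1 library was left out its group kept 2.

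Each comparison was tested on simulated data for the 20,034 genes kept by the filter, with 100 genes changed 2-fold and 100 changed 4-fold. The changed genes were drawn only from genes above a minimum mean count, so the recovery does not cover genes of low counts. Recovered were 49% and 78% for challenge in wild type (19,213 genes kept, 7 false calls), 56% and 76% for challenge in the knockout (19,233 genes, 5 false), and 44% and 82% for genotype when sensitized (19,341 genes, 4 false). For genotype when challenged it was 51% and 76% (19,278 genes, 4 false), and for the interaction 35% and 75% (19,235 genes, 5 false). The averaged genotype effect gave 67% and 89% (19,306 genes, 4 false) and the averaged challenge effect 68% and 93% (19,223 genes, 10 false). Camera called the 1 changed list in each comparison and 0 unchanged lists. Genes were simulated independently of one another, so this does not test the preset correlation.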

Results

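Mandibular lymph nodes of wild-type mice and of mice lacking the microRNA miR-451a (knockout) were compared after sensitization of the skin with the contact allergen 1-fluoro-2,4-dinitrobenzene (DNFB). Per the labels, 100 µl of 0.5% DNFB was put on the shaved abdomen on days 0, 1 and 2. Nodes were taken on day 9 (groups WT_se and KO_se), or on day 10, 24 hours after 20 µl of 1% DNFB on the left ear (WT_DTH and KO_DTH). All challenged nodes were thus taken on day 10 and all others on day 9. What is called an effect of challenge below therefore cannot be told apart from an effect of the day of harvest. Each of the 4 groups held 3 libraries of total RNA, 12 in all, with 36,946,696 to 58,405,576 estimated counts per library. The study asks how loss of miR-451a changes the allergic response in secondary lymphoid tissue, above all that of the cytokine IL-17A. Mir451a itself was not analysed here. Its cluster neighbour Mir144 held 0 counts in the 6 wild-type libraries and 0 to 2 in the 6 knockout libraries, too few to test, so the targeted gene gave no check of the knockout label in any library. Xist counts exceeded those of the Y-linked gene Ddx3y in 1 of 3 WT_se, 2 of 3 WT_DTH, 1 of 3 KO_se and 2 of 3 KO_DTH libraries, so every group held both sexes.

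Transcripts of salivary gland were present in every library, and their share differed between groups. The 20 salivary genes followed took 10.4 ± 3.71% of counts in WT_se, 2.54 ± 0.668% in WT_DTH, 4.52 ± 1.98% in KO_se and 7.48 ± 2.91% in KO_DTH (mean ± SD, n = 3 each). The share thus lay lower after challenge in wild type (difference −7.86 points, two-sided exact permutation p = 0.1) and lower in the knockout than in wild type when sensitized (−5.88 points, exact p = 0.1). It lay higher in the knockout when challenged (4.94 points, exact p = 0.1), while challenge in the knockout gave 2.97 points (exact p = 0.3). With 3 libraries against 3 the smallest p possible is 0.1. Mitochondrially encoded genes took 17.3 ± 2.88%, 5.29 ± 0.746%, 13.9 ± 2.12% and 10.7 ± 5.16% of counts in WT_se, WT_DTH, KO_se and KO_DTH, and erythroid genes 1.10 ± 0.386%, 0.248 ± 0.0168%, 0.870 ± 0.627% and 0.292 ± 0.174%. Every comparison below was therefore also fitted with 2 components of the salivary genes as covariates, a choice made after these shares were seen.

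**Figure D1:**
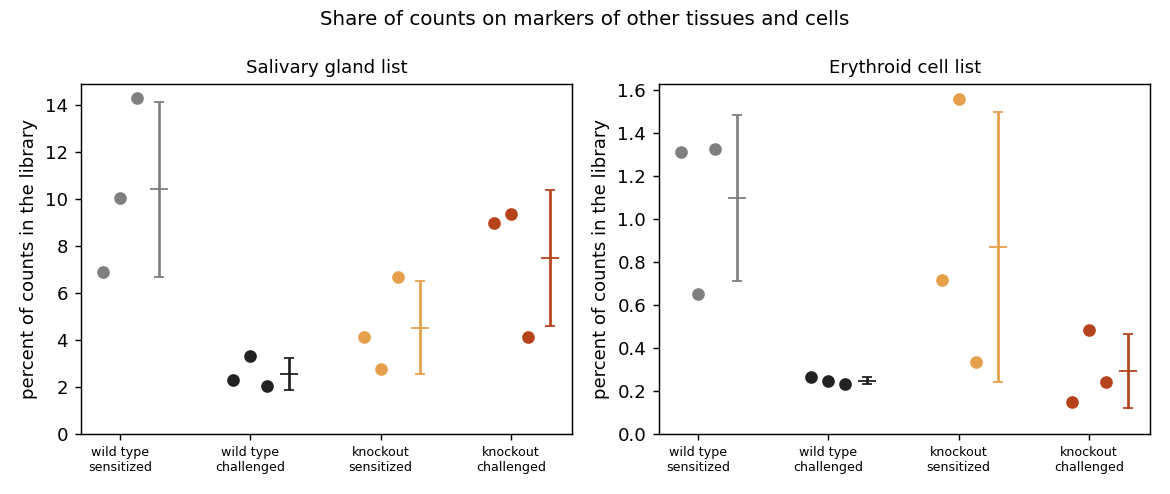
Share of all estimated counts held by salivary gland genes and by erythroid genes in each library, by group. Points are libraries, and bars are the group mean ± SD over 3 libraries.

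The first comparison asks what differs in the wild-type node 24 hours after a challenge of the ear, any effect of harvest day included. Interferon-induced genes rose. Stat2 (ENSMUSG00000040033), a transcription factor that carries type I interferon signals, rose from 34.5 ± 0.842 to 142 ± 15.3 CPM (counts scaled to library size; mean ± SD, n = 3; log2 fold change 2.04 ± 0.15 SE, adjusted p = 1.61e-05). Cxcl10 (ENSMUSG00000034855), a chemokine that draws activated T cells, rose by 2.74 ± 0.20 in log2 (adjusted p = 1.61e-05) and passed in all 16 other settings tried. Oasl2, a sensor of the antiviral response, rose by 2.88 ± 0.31 and Gbp2, a guanylate-binding protein from a family of close copies, by 2.19 ± 0.17. All 20 type I interferon genes rose (20 adjusted over the list alone), with a median log2 fold change of 2.18 (SD over members 0.58; camera, adjusted p = 2.53e-17). Of 20 interferon-γ response genes, 17 rose and 1 fell (the same adjusted over the list alone; median 1.24, adjusted p = 4.08e-13). With an estimated correlation both lists gave an adjusted p = 0.255.

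Genes of myeloid cells also rose in wild-type nodes, and those of naive T cells fell. Fcgr1, the high-affinity IgG receptor of monocytes, rose by 3.42 ± 0.34 in log2 (adjusted p = 5.43e-05). Of 13 monocyte genes 10 rose (11 adjusted over the list alone; median 1.57, adjusted p = 7.47e-10, or 0.255 with an estimated correlation). Neutrophil genes rose in 10 of 18 (12 alone; median 1.41, adjusted p = 2.34e-06, or 0.28 estimated), and MHC class II genes in 10 of 11 (10 alone; median 0.85, adjusted p = 2.4e-08, or 0.255 estimated). B cell genes rose in 10 of 14 (13 alone; median 0.67, adjusted p = 4.28e-06, or 0.371 estimated). Of 18 naive and resting T cell genes 15 fell and 1 rose (the same alone; median −0.64, adjusted p = 6.38e-08, or 0.255 estimated), among them the costimulatory receptor Cd28 (−1.16 ± 0.15, adjusted p = 0.000302). Ifng rose by 1.74 ± 0.33 (adjusted p = 0.00312). Il22 rose by 3.34 ± 0.81 (adjusted p = 0.0123) from a mean of 0.0893 CPM, and the Th1 regulator Tbx21 by 0.71 ± 0.22 (adjusted p = 0.0408), a call lost in 5 of the 6 fits that left out 1 library. Il17a did not pass (0.48 ± 0.36, adjusted p = 0.418), and neither did Il17f, Il23r, Ccr6, Il4, Il13, Gata3, Foxp3 or Il10. The IL-17 response list was called higher all the same (5 of 14 rose, 7 alone; median 1.07, adjusted p = 0.0151, or 0.255 estimated), a call also lost with either salivary covariate.

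In the same comparison 18 of 20 salivary genes fell (20 adjusted over the list alone; median −3.24, adjusted p = 1.5e-09), as did all 13 mitochondrially encoded genes (13 alone; median −2.07, adjusted p = 2.35e-10) and 7 of 13 erythroid genes (9 alone; median −2.50, adjusted p = 7.11e-06). With an estimated correlation each of these 3 lists gave an adjusted p = 0.255, and the salivary direction reversed with the salivary score (0.855). Examples are the keratin Krt18 of gland epithelium (−3.15 ± 0.50, adjusted p = 0.00115), mt-Nd5 (−2.19 ± 0.31, adjusted p = 0.000514) and the α-globin Hba-a1 (−2.63 ± 0.55, adjusted p = 0.0057). By edgeR 3755 of 20,034 genes passed, 1957 higher and 1798 lower, 1518 of them by more than 2-fold. Leaving out 1 library gave 2566 to 3136. With the 2 salivary covariates 49 of the 3755 still passed. The median size of the 3755 went from 0.77 to 0.56 in log2 and their median SE from 0.16 to 0.31, and 96.4% kept their direction.

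The second comparison asks the same of the knockout node. The interferon rise was there too: Stat2 rose by 1.99 ± 0.15 in log2 (adjusted p = 2.78e-05), Gbp2 by 2.33 ± 0.17 (adjusted p = 1.6e-05) and Irgm1 (ENSMUSG00000046879), an interferon-induced GTPase, by 2.14 ± 0.13 (adjusted p = 7.23e-06). These 3 and Fcgr1 (3.73 ± 0.34, adjusted p = 5.14e-05) passed in all 16 other settings. All 20 type I interferon genes rose (20 adjusted over the list alone; median 2.81, SD 0.68, adjusted p = 4.09e-26, or 0.258 with an estimated correlation), and 16 of 20 interferon-γ response genes did (16 alone; median 1.47, adjusted p = 1e-15, or 0.207 estimated). Monocyte genes rose in 8 of 13 (9 alone; median 1.40, adjusted p = 1.86e-07, or 0.258 estimated). Ifng rose by 1.43 ± 0.32 (adjusted p = 0.0148), a call lost without KO_se replicate 2 or KO_DTH replicate 2.

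Il17a fell on challenge in the knockout, from 21.4 ± 7.59 to 7.50 ± 1.42 CPM (−1.51 ± 0.29, adjusted p = 0.00648), a call kept without any 1 of the libraries. Its change differed from that in wild type (interaction −1.99, adjusted p = 0.0476). But the interaction call was lost in each of the 12 fits that left out 1 library (adjusted p 0.0525 to 0.117) and with either salivary covariate. It was also lost with no filter (0.0549), the replicate block (0.0721), sex as covariate (0.0522) and without the libraries of largest salivary share (0.164). The interaction fold stayed at −1.7 to −2.22 without 1 library. With larger SEs, it was −2.19 ± 0.96 with the salivary score and −2.52 ± 0.86 with 2 components. Il17f fell by 1.77 in log2 (SE 0.47, adjusted p = 0.0326), but this was lost in 5 of the 6 fits without 1 library, and its interaction did not pass (−2.62, adjusted p = 0.0697). Cd209b and Timd4, receptors of resident macrophages, fell (−2.94 ± 0.34, adjusted p = 0.000178, and −2.68 ± 0.33, adjusted p = 0.000323), and so did the mitotic kinesin Kif11 (−0.91 ± 0.19, adjusted p = 0.00837). All 3 passed in all 16 other settings. The macrophage list as a whole went the other way (6 of 14 rose and 1 fell, 8 and 2 adjusted over the list alone; median 0.54, adjusted p = 0.0138, or 0.532 with an estimated correlation). Of 30 cell cycle genes 5 fell (10 adjusted over the list alone; median −0.49, adjusted p = 0.000116, or 0.532 with an estimated correlation). Of 15 mast cell, basophil and eosinophil genes 4 fell (4 alone; median −1.36, adjusted p = 0.00049, or 0.31 estimated), led by the mast cell protease Cpa3 (−2.12 ± 0.38, adjusted p = 0.00437). Jchain, which joins the units of secreted IgA and IgM, fell by 2.01 (SE 0.43, adjusted p = 0.0117).

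Salivary genes rose in this comparison in 2 of 20 (4 adjusted over the list alone; median 1.73, adjusted p = 0.0103, or 0.575 with an estimated correlation), a list call lost without KO_DTH replicate 2, and its direction reversed with the salivary score (adjusted p = 0.2) and with 2 salivary components (0.259). By edgeR 1938 genes passed, 1164 higher and 774 lower, 526 by more than 2-fold. Leaving out 1 library gave 1039 (without KO_DTH replicate 1) to 1772, and leaving out the library of largest salivary share in each group gave 673. With the 2 salivary covariates 379 of the 1938 still passed. Their median size went from 0.58 to 0.62 over all 1938 and the median SE from 0.12 to 0.20, with 99.9% keeping their direction.

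**Figure D2:**
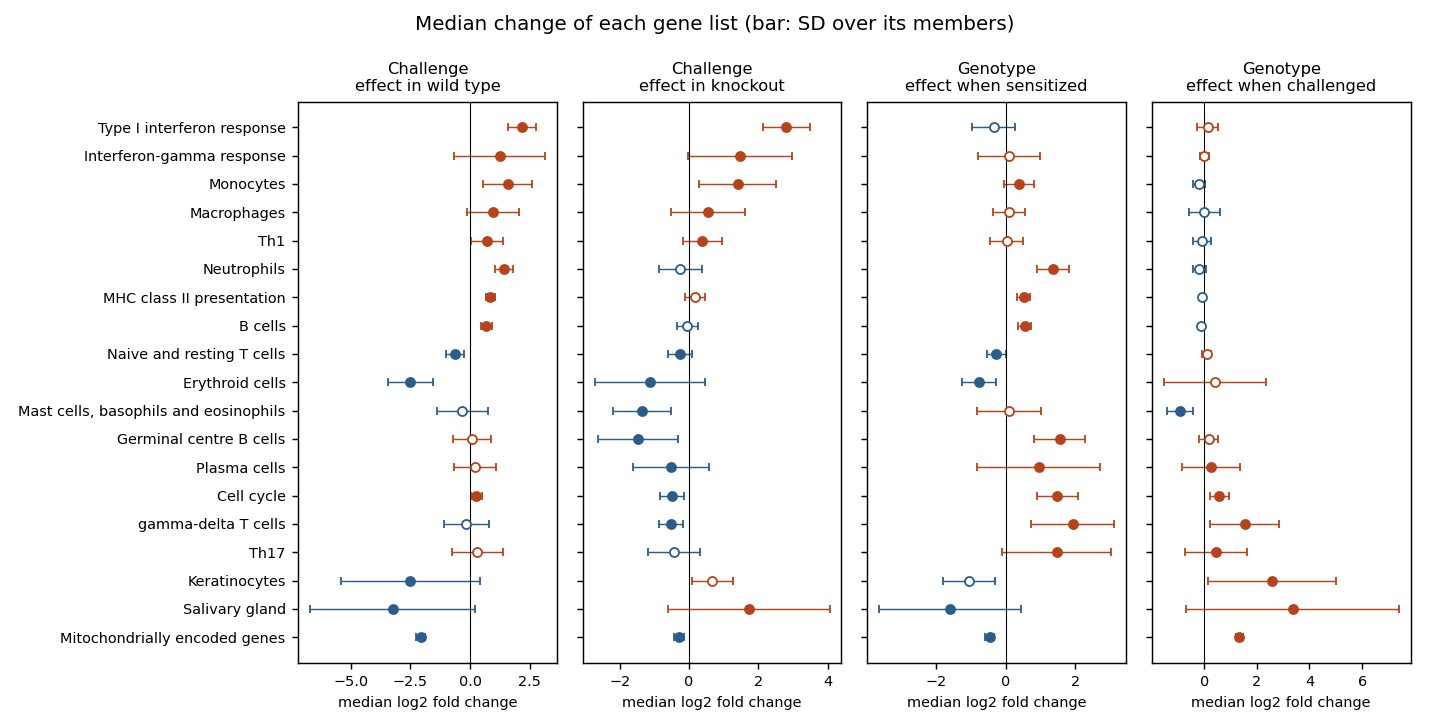
Median log2 fold change of 19 gene lists in the comparisons of pairs of groups, with bars for the SD over list members. Filled symbols are lists called by camera with the preset correlation (red higher, blue lower), and open symbols are lists not called.

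The third comparison asks how the knockout node differs from the wild-type node after sensitization alone. Genes of IL-17-producing and γδ T cells rose. Il17a (ENSMUSG00000025929), the cytokine the study centres on, rose from 0.554 ± 0.184 to 21.4 ± 7.59 CPM (n = 3; log2 fold change 5.26 ± 0.36, adjusted p = 1.6e-05) and passed in all 16 other settings. Il17f, a related cytokine, rose by 3.88 ± 0.53 (adjusted p = 0.00218). The γδ T cell receptor constant genes Tcrg-C1 (ENSMUSG00000076749) and Trdc rose by 2.97 ± 0.25 (adjusted p = 0.000144) and 1.89 ± 0.23 (adjusted p = 0.00148). Cd163l1, a scavenger receptor of γδ T cells, rose from 7.82 ± 2.07 to 73.1 ± 9.24 CPM (3.22 ± 0.37, adjusted p = 0.00128). Of 12 γδ T cell genes 9 rose (11 adjusted over the list alone; median 1.93, SD over members 1.19, adjusted p = 1.6e-13, or 0.0644 with an estimated correlation). Of 18 Th17 genes 8 rose (13 alone, with 1 lower; median 1.47, adjusted p = 1.73e-09, or 0.0644 estimated). Il23r (1.58 ± 0.35, adjusted p = 0.023) and Il22 (3.20 ± 0.80, adjusted p = 0.0389) rose as well, but these calls were lost in 4 and 6 of the 6 fits that left out 1 library. Ifng (−0.05 ± 0.33, adjusted p = 0.958), Tbx21 (−0.25 ± 0.22, adjusted p = 0.569) and Foxp3 (−0.10 ± 0.12, adjusted p = 0.697) did not pass, nor did Ccr6, Il4, Il13, Gata3 or Il10.

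Genes of dividing cells and of antibody secretion were higher as well. Of 30 cell cycle genes 27 rose (30 adjusted over the list alone; median 1.49, adjusted p = 2.68e-27, or 0.235 with an estimated correlation), among them the kinase Cdk1 of mitotic entry (2.22 ± 0.25, adjusted p = 0.00128) and Kif11 (1.67 ± 0.19, adjusted p = 0.00128). Igha (ENSMUSG00000095079), the constant region of IgA, rose from 7.12 ± 0.587 to 262 ± 33.6 CPM (5.20 ± 0.49, adjusted p = 0.000275), though immunoglobulin constant genes are close copies of one another. Plasma cell genes rose in 9 of 17 and fell in 1 (12 and 2 alone; median 0.95, adjusted p = 7.49e-05, or 0.359 estimated). Neutrophil genes rose in 6 of 18 (13 alone; median 1.36, adjusted p = 1.36e-08, or 0.36 estimated), among them the alarmin S100a8 (2.11 ± 0.39, adjusted p = 0.00988). For the unfolded protein response list the median (0.22), the mean (−0.01) and the test (higher, adjusted p = 0.0107, or 0.471 estimated) differed in sign. Naip6 (7.13 ± 0.65, adjusted p = 0.000756), an inflammasome sensor, rose and Slfn8 (−2.69 ± 0.19, adjusted p = 1.6e-05), a schlafen family member, fell; both have near-identical copies, so which copy changed is uncertain.

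Salivary genes were lower as a list (1 of 20 fell, 12 alone; median −1.59, adjusted p = 2.61e-07, or 0.361 with an estimated correlation), a direction that reversed with the salivary score (adjusted p = 0.753). Mitochondrially encoded genes were called lower (0 of 13 fell, 0 alone; median −0.46, adjusted p = 0.0126, or 0.784 estimated), but their direction reversed with the salivary score (adjusted p = 0.0698) and with 2 salivary components (0.487). By edgeR 1035 genes passed, 754 higher and 281 lower, 309 by more than 2-fold. Leaving out 1 library gave 369 (without KO_se replicate 2) to 748. With the 2 salivary covariates 22 still passed, with the median size unchanged at 0.62 and the median SE going from 0.13 to 0.21. Il17a, Tcrg-C1, Igha, Cdk1, Kif11, Naip6 and Slfn8 passed in all 16 other settings, these covariates included.

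**Figure D3:**
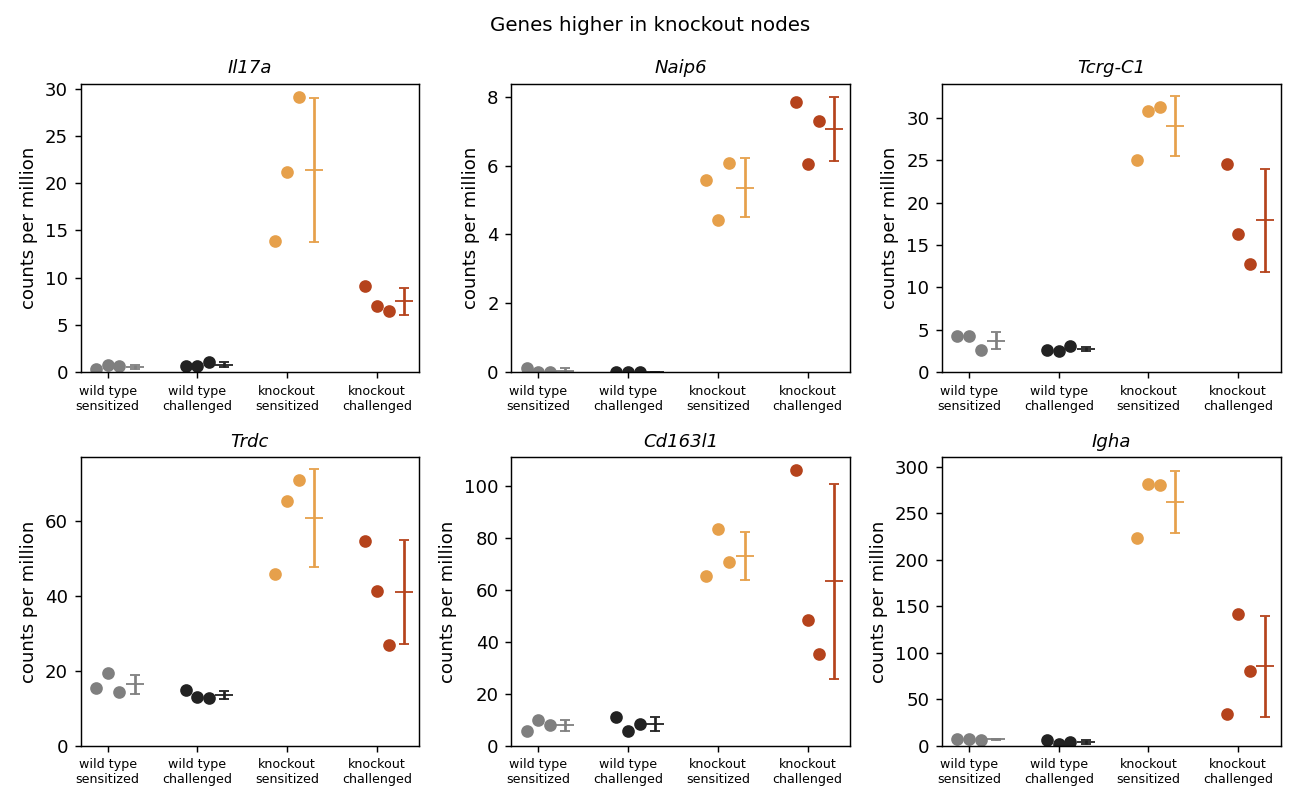
CPM of Il17a, Naip6, Tcrg-C1, Trdc, Cd163l1 and Igha in each library, by group. Points are libraries, and bars are the group mean ± SD over 3 libraries.

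The fourth comparison asks the same after challenge. Il17a stayed higher in the knockout (0.772 ± 0.261 against 7.50 ± 1.42 CPM, n = 3; log2 fold change 3.27 ± 0.33, adjusted p = 0.000819). Tcrg-C1 (2.72 ± 0.25, adjusted p = 0.000381), Cd163l1 (2.92 ± 0.36, adjusted p = 0.00396) and Igha (4.53 ± 0.48, adjusted p = 0.00125) were higher too. Of 12 γδ T cell genes 8 rose (10 adjusted over the list alone; median 1.55, SD 1.31, adjusted p = 8.57e-13, or 0.119 with an estimated correlation). Of 18 Th17 genes 4 rose (9 alone, with 2 lower; median 0.44, adjusted p = 0.00175, or 0.361 estimated). Naip6 was at least 369-fold higher (0 counts in all WT_DTH libraries; adjusted p = 0.000328). Slfn8 (−2.50 ± 0.18, adjusted p = 5.04e-05) and the helicase gene Dhx40 (−1.26 ± 0.11, adjusted p = 0.000213) were lower. Each gene named so far in this paragraph passed in every fit that left out 1 library and was lost with the 2 salivary covariates, where their SE grew. With those covariates the log2 fold change was 2.78 ± 0.55 for Il17a, 3.0 ± 0.53 for Tcrg-C1, 3.58 ± 0.64 for Cd163l1, 3.45 ± 0.74 for Igha, −2.02 ± 0.33 for Slfn8 and −1.03 ± 0.24 for Dhx40. For Naip6 the fitted value went from 11.34 ± 0.87 to 11.24 ± 1.5, a size poorly defined against a group at 0 counts. Il17f did not pass (1.27 ± 0.48, adjusted p = 0.241; interaction −2.62, adjusted p = 0.0697), and neither did Ifng, Tbx21, Il22, Il23r, Ccr6, Il4, Il13, Gata3, Foxp3 or Il10.

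No cell cycle gene of 30 passed over all genes by edgeR, while 13 did adjusted over the list alone (median 0.57, adjusted p = 1.04e-09, or 0.496 with an estimated correlation). Salivary genes were higher (2 of 20 rose, 15 alone; median 3.36, adjusted p = 1.04e-09, or 0.361 estimated), with Krt18 at 3.33 ± 0.50 (adjusted p = 0.0159), a call lost in 5 of the 6 fits without 1 library. Mitochondrially encoded genes were higher as a list (0 of 13 rose, 13 alone; median 1.34, adjusted p = 6.71e-09, or 0.496 estimated). Both list directions reversed with the salivary score. By edgeR 120 genes passed, 103 higher and 17 lower, against 2832 with an unadjusted p below 0.05. With the replicate block 38 passed, with no filter 64, with sex as covariate 265 and by the DESeq2 Wald test 932. The count went from 14 (without WT_DTH replicate 1) to 471 (without KO_DTH replicate 3), and 1 of the 120 passed with the 2 salivary covariates, with the median size going from 2.29 to 1.02 and the median SE from 0.39 to 0.62.

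Whether challenge acts differently in the genotypes was tested as an interaction, positive where the change on challenge was greater in the knockout. By edgeR 422 genes passed, 334 positive and 88 negative, while 128 passed with the replicate block and 1238 by the DESeq2 Wald test. The positive ones of smallest p, not of largest fold, included Acta2 of smooth muscle and myoepithelium (3.99 ± 0.53), Krt18 (4.83 ± 0.68) and the metallothionein Mt1 (2.34 ± 0.34), each with an adjusted p = 0.0237. Of 20 salivary genes 12 were positive (20 adjusted over the list alone; median 4.95, adjusted p = 6.03e-15, or 0.384 with an estimated correlation), and 1 of 13 mitochondrially encoded genes was (13 alone; median 1.75, adjusted p = 6.74e-09, or 0.413 estimated). The negative ones included Ly86 of B and myeloid cells (−0.90 ± 0.13, adjusted p = 0.0237). Each of these 4 genes was lost without WT_DTH replicate 3, KO_se replicate 1 or KO_se replicate 2. Of 14 B cell genes 2 were negative (12 alone; median −0.68, adjusted p = 1.68e-07, or 0.441 estimated), and of 30 cell cycle genes 2 were (18 alone; median −0.84, adjusted p = 3.06e-12, or 0.384 estimated). No type I interferon gene passed over all genes by edgeR, and 1 did alone (median 0.49, adjusted p = 0.0156, or 0.802 estimated). The direction of the salivary, mitochondrial and type I interferon lists reversed with the salivary score. None of the 422 passed with the 2 salivary covariates (median size from 2.95 to 0.67, median SE from 0.59 to 1.04). Leaving out 1 library gave 0 (without WT_DTH replicate 3) to 830 (without KO_DTH replicate 3).

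Averaged over both states, with 6 libraries against 6, the genotype effect passed in 950 genes, 595 higher and 355 lower in the knockout. Of 12 γδ T cell genes 11 rose (11 adjusted over the list alone; median 1.83, SD 1.12, adjusted p = 7.36e-18). This was the only list call in any comparison that held with an estimated correlation (adjusted p = 0.0462), and that was lost without any of 10 of the 12 libraries (up to 0.118). Th17 genes rose in 9 of 18 and fell in 1 (12 and 2 alone; median 1.01, adjusted p = 7.57e-09, or 0.079 estimated). Cell cycle genes rose in 24 of 30 (30 alone; median 0.95, adjusted p = 1.05e-27, or 0.227 estimated). With the 2 salivary covariates 271 of the 950 still passed, the median size of the 950 going from 0.39 to 0.38 and their median SE from 0.08 to 0.1. Leaving out 1 library gave 412 (without WT_DTH replicate 2) to 1012. Without the library of largest salivary share in each group, which leaves 2 per group, 112 genes passed, 104 of them among the 950. The challenge effect averaged over both genotypes passed in 4306 genes, 2373 higher and 1933 lower. Of these 3392 passed with the covariates, and leaving out 1 library gave 3434 to 4017. All 20 type I interferon genes rose in it (20 alone; median 2.55, adjusted p = 1.11e-22, or 0.225 estimated). The lists of Th2 cells, regulatory T cells, cytotoxic and NK cells, migratory dendritic cells, platelets, skeletal muscle and high endothelial cells were not called in any comparison.

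Predicted and reported targets of miR-451a were compared between genotypes to ask whether they rise without the microRNA. Of 327 tested genes with a 7-base match to its seed in the 3′ UTR, 9 rose and 5 fell in the averaged genotype effect. Their median log2 fold change was −0.002, against 0.027 for the other genes with a searched 3′ UTR (camera p = 0.25, or 0.0518 with an estimated correlation). When sensitized 9 rose and 5 fell, and when challenged 1 rose and 0 fell. Their medians were −0.035 against −0.002 when sensitized (camera p = 0.441, or 0.165 with an estimated correlation) and −0.025 against 0.015 when challenged (p = 0.345, or 0.0981 estimated). The 71 genes with the longer seed match gave a camera p = 0.43 in the averaged effect, or 0.334 with an estimated correlation. The list of reported targets was not called either (median 0.00, 0 rose and 1 fell, adjusted p = 0.79).

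Genes on chromosome 11 around Mir451a were set apart because they lie beside the altered sequence. A list of 43 genes near the locus, fixed in advance, was not called by camera in the averaged genotype effect (3 rose and 3 fell, adjusted p = 0.878). Camera asks for a shift in 1 direction, so it cannot decide on changes that go both ways. Of all tested genes 950 of 20,034 passed in this effect. Slfn8, which fell in the knockout in both states, lies 75 tested genes from the locus, and Dhx40 136.

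**Figure D4:**
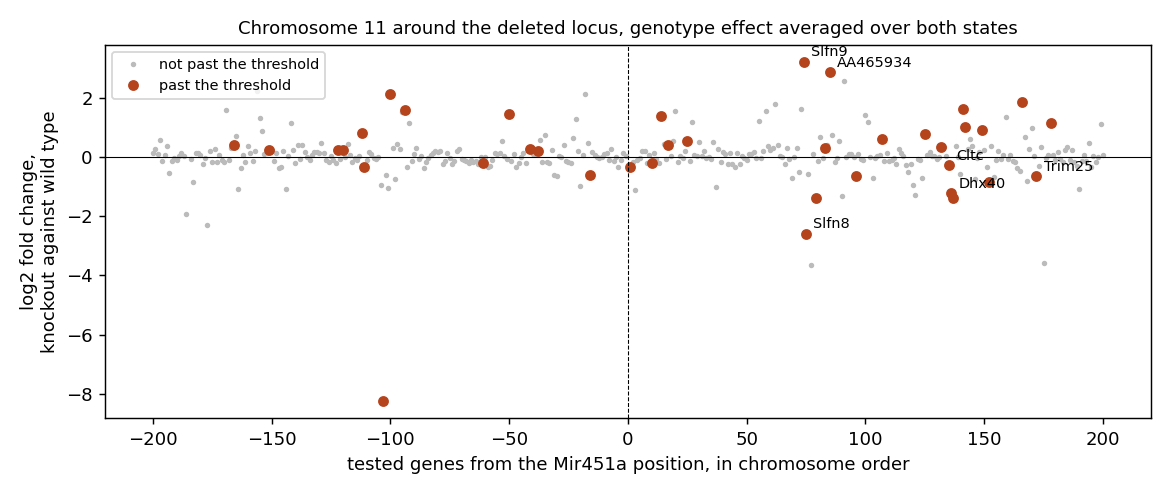
Averaged genotype effect (log2 fold change) of 200 tested genes on each side of Mir451a on chromosome 11, in gene order. Red points passed the threshold, and the genes given a label were picked after their values were seen.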

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

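The tests chosen only after the result was seen are that of salivary tissue against the interaction, the splits with the averaged genotype effect taken out, and all fits with salivary covariates or sex. The results here stood out because the effect of challenge differed between wild type and knockout by the interaction term of the edgeR model or, for lists, by camera. Values are interaction log2 fold changes, or medians over list members, positive where the change on challenge was greater in the knockout. The lists are salivary gland 4.95, keratinocytes 3.63, mitochondrially encoded genes 1.75, erythroid cells 0.92, type I interferon response 0.49, immediate early and heat shock genes 0.42, naive and resting T cells 0.29, resident dendritic cells −0.38, Th17 −0.51, monocytes −0.54, MHC class II presentation −0.62, B cells −0.68, plasma cells −0.69, germinal centre B cells −0.78, IL-17 response −0.78, cell cycle −0.84, mast cells, basophils and eosinophils −0.87, and neutrophils −1.57. None of these list calls held with an estimated correlation. The direction reversed with the salivary score and with 2 salivary components for salivary gland, monocytes, mast cells and neutrophils. It reversed with the score alone for keratinocytes, mitochondrially encoded genes, erythroid cells and type I interferon, and with 2 components alone for immediate early genes. The genes are Prol1 14.36, Dcpp2 11.88, Krt18 4.83, Acta2 3.99, Mt1 2.34, Ly86 −0.90, Cdk1 −1.53 and Il17a −1.99 (Dcpp2 has near-identical copies, so which copy changed is uncertain). Other splits of the genotype labels within each state gave as many as the real 422 genes in 3 of 100 splits, the real one included. These splits also mix the averaged genotype effect into the spread, so alone they do not test the interaction. The highest of the others, 950, came from the split that exchanges genotype in 1 state, which turns the interaction into the averaged genotype effect. The next, 708, exchanged 2 of the 3 challenged libraries of each genotype. With the averaged genotype effect taken out of each gene, the real split gave 422 genes, those 2 splits gave 0 (the first by construction) and the highest of the others gave 3. The real split was thus 1 of 100, the smallest share these splits can give. The averaged effect taken out was estimated from the real labels, in a version chosen after the first count was seen, so chance is not excluded. A cause tied to single libraries stays open too: 0 genes passed without WT_DTH replicate 3, KO_se replicate 1 or KO_se replicate 2.

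A first pattern is the set of genes with a positive interaction, for which salivary gland tissue taken with the node is a candidate source. Within groups, the 322 such genes outside the salivary list had a median correlation of 0.58 with the salivary score, against 0.06 at the 95th percentile and 0.1 at most in 1000 random sets matched on expression. With 2 salivary components as covariates, the median over all 334 positive genes went from 3.31 ± 2.80 (SD) to 0.60 ± 1.93. These 334 include 12 members of the salivary list, from which the covariates were built. Of the 334, 0 stayed past the threshold, in part because the median SE over all 422 rose from 0.59 to 1.04. These values go with salivary tissue as the source of much of the positive part. The negative part had a median correlation of −0.09 with the score and a median of −0.87 that became −0.71, so it stays open, as does the Il17a interaction (−2.52 with the covariates, adjusted p = 1, and lost without any 1 of the 12 libraries). A biological difference between genotypes in how challenge acts was not excluded.

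A second pattern is the higher level of γδ T cell and Th17 genes in knockout nodes. The 11 γδ T cell genes that passed in the averaged genotype effect had a median of 1.92 ± 1.01 (SD). With 2 salivary components it was 1.87 ± 1.00, 10 still passed, and the Th17 median went from 1.01 to 0.96. This fit cannot decide on salivary tissue, since the salivary difference between genotypes (−5.88 points sensitized, 4.94 challenged) largely cancels in that average. For all 950 genes called there, the median size likewise went from 0.39 to 0.38. The γδ T cell list was higher in the knockout in both states though, which argues against salivary share as its only source. Against a lower share of the main cell type lifting all others alike, the lists of 6 other leukocyte types all lay below the γδ T cell median of 1.83 by more than their SD, the lowest, cytotoxic and NK cells, at −0.09. Against 1 deviating library, the median without any 1 of the 12 libraries stayed at 1.82 to 2.09 with a preset adjusted p of at most 2.97e-16. With sex as covariate the median was 1.92 ± 1.01 and all 11 genes still passed. That fit could hardly have moved the median, since within each state both genotypes held the same number of each sex. By that balance, a sex effect alike in both genotypes does not account for the difference. The prediction written for the test of 1 library named the call with an estimated correlation. That call was lost on leaving out any of 10 of the 12 libraries (highest adjusted p = 0.118). It was kept without KO_DTH replicate 1 (0.0208) or 3 (0.0266). Whether fewer samples alone gave the losses was not tested. By that prediction 1 deviating library stays open for the call, though the median, over genes chosen with all 12 libraries, held without each. The values are in line with more γδ and IL-17-producing T cells, or more of these transcripts per cell, in knockout nodes, a hypothesis found and tested on the same data, while sequence carried with the knockout allele stays open.

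Other splits of the 12 libraries were also counted for the other results. For the averaged genotype effect 1 of 100 splits, the real one, gave its 950 genes. The highest other, 422, came from the split that exchanges genotype in the challenged state, which turns this effect into the interaction. For the averaged challenge effect 1 of 100 gave its 4306 (highest other 946). A share of 1 of 100 is the smallest these splits can give, and the other splits mix the real effect into their spread. The labels do not say whether the libraries come from separate animals, so chance is not excluded. For the comparisons of 3 libraries with 3 only 10 splits exist, too few for a share under 0.05. The real splits gave 3755, 1938, 1035 and 120 genes for challenge in wild type, challenge in the knockout, genotype when sensitized and genotype when challenged, and the highest other split gave 1 in each.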

How the results depend on the processing

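Tests with salivary covariates, without the library of largest salivary share, and with sex as covariate were chosen only after the data were seen; the rest were planned. Comparisons are written A (challenge, wild type), B (challenge, knockout), C (genotype, sensitized), D (genotype, challenged), E (interaction), F (averaged genotype) and G (averaged challenge). DESeq2 size factors kept every count within 1.5 times, as did a mean of at least 50 counts and fits of only the libraries compared, and kept 403 of 406 named gene results. Genes passing were, with the salivary score, A 22, B 588, C 15, D 1, E 0 and F 587, and with 2 salivary components A 51, B 423, C 25, D 1, E 0 and F 303, where SEs grew. Without the library of largest salivary share, with 2 libraries per group, they were A 2464, B 673, C 351, E 168, F 112 and G 2833. The DESeq2 Wald test gave B 2952, C 2280, D 932, E 1238 and F 1964; no filter gave D 64, E 267 and F 601, with more genes tested; sex as covariate gave D 265. With replicate number as a block D was 38 and E 128, and the Il17a interaction was at an adjusted p = 0.0721. Within a state every wild-type library correlated best with its own number in the knockout (0.043 to 0.141 between WT_se and KO_se, 0.067 to 0.078 between WT_DTH and KO_DTH), a hint from the data and not from the design. The best match of each knockout library among wild-type ones was not computed. Same-numbered libraries within a state also shared their sex by Xist and Ddx3y counts, and whether shared sex gives these correlations was not tested. Most of them lie under 0.1 and the labels give the numbers no meaning, so the numbers were not taken to pair the samples. Between states KO_se and KO_DTH gave −0.015 to −0.098, which does not bear on pairs within a state. Lists called with an estimated correlation were A 0, B 0, C 0, D 0, E 0, F 1 and G 0, with fry B 12, C 12, D 4, E 1 and F 10, with 2 components D 6 and E 4, and with the salivary score E 6. Leaving out 1 library gave A 2566 to 3136 genes and 17 to 20 lists, B 1039 to 1772 and 20 to 22, C 369 to 748 and 14 to 20, D 14 to 471 and 12 to 15, E 0 to 830 and 12 to 19, F 412 to 1012 and 15 to 18, and G 3434 to 4017 and 18 to 23. With the salivary score the direction reversed, at these adjusted p, for salivary gland (A 0.855, B 0.2, C 0.753, D 0.29, E 0.486), mitochondrially encoded genes (C 0.0698, D 0.669, E 0.252), fibroblastic stroma (D 0.957), oxidative phosphorylation (D 0.939), keratinocytes (E 0.98), monocytes (E 0.98), and erythroid cells, mast cells, neutrophils and type I interferon (E 0.956 each). With 2 components it reversed for salivary gland (B 0.259, D 0.733, E 0.996), mitochondrially encoded genes (C 0.487), immediate early genes (D 0.554, E 0.773), mast cells (E 0.923), monocytes (E 0.902) and neutrophils (E 0.902). None of these reversed values passed. Among genes that passed and were named in that same comparison, folds reversed for Col3a1 0.16, Fabp4 0.28 and Dcpp2 0.99 (A, score), and Prol1 −0.91 and Cpt1b 0.21 (B, 2 components). For salivary genes the covariate is built from the list itself; for the rest the cause was not tested. Of 406 named gene results 164 stayed on their side with the score and 168 with 2 components (239 and 236 weaker), 375 with no filter (31 weaker), 367 with the block (37 weaker), 383 with sex (13 weaker), and 344 of 386 with the Wald test (42 newly past). Of 125 list calls 73 stayed with the score, 70 with 2 components, 72 with fry and 124 each with size factors, no filter, the block and sex. Alternatives for normalized values (pseudocounts, quantile scaling) gave no value, since the values are counts. At this depth Mir144 and genes near 0 counts could not be tested.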

Other observations

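The tests of gene position below were chosen only after the result was seen; the seed test was written before.

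The third pattern is a raised share of genotype calls in a wide stretch of chromosome 11 around Mir451a: among the 100 tested genes on each side 18 of 200 (9%) passed in the averaged genotype effect, against 932 of 19,834 elsewhere (4.7%; odds ratio 2.01, Fisher's exact test p = 0.0105) and 82 of 1244 on the rest of the chromosome (6.6%; odds ratio 1.40, Fisher's exact test p = 0.229). The share did not peak at the locus: before and after it, it was 8% and 10% in the nearest 50 genes, 6% and 12% in the next 50, 7% and 13% in the 100 beyond those, and 3% and 5% in the 200 beyond those. The first of these tests restates what prompted it and the other did not pass, so variants inherited with the knockout allele stay open, also for Slfn8 (−2.59 ± 0.13) and Slfn9 (3.21 ± 0.11, chosen after its values were seen). Other large changes past the threshold were Xaf1 (1.59 ± 0.19), AA465934 (2.86 ± 0.23) and, 103 tested genes before the locus, Nlrp1a (−8.25). These 3 were also picked after their values were seen. As to lost repression by the microRNA, 0 of the 15 called genes near the locus with a searched 3′ UTR carried a seed match (0%, against 2.3% of all searched genes). Direct repression through such a match therefore does not account for these 15. At 2.3% a count of 0 in 15 is likely whatever the cause, so it cannot decide on other routes. Reads shared between the close copies Slfn8 and Slfn9 stay open for those 2 genes, and no sequence was examined.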
